A study of Dictyostelium discoideum AX2 with 112 samples.

How the data were processed

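Cells of Dictyostelium discoideum AX2, a social amoeba that grows as single cells and builds a multicellular fruiting body when starved, were grown at 22 °C in axenic medium. They were washed, spread on non-nutrient agar, held in the cold for 9 h to synchronise them, and developed at 22 °C, per the labels' protocols. The 112 samples fall into 56 groups of 2: 7 strains (wild type and knockouts of the polyketide synthase genes pks1, pks2, pks3, pks14, pks18 and pks37) at 8 stages. The design text lists a starvation stage where the sample labels have T0, and T0 is taken for it here by elimination. In each group replicate 1 carried Cy3 and replicate 2 Cy5, per the labels' labelling protocol. No label says whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

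RNA was amplified, labelled and hybridised to 56 two-colour Agilent arrays on 7 slides, with different samples in the 2 channels of an array, per the labels. Each stage other than T0 lay on a slide of its own, with all 7 strains on it, while the T0 samples were spread over the 7 slides. Strains were therefore compared within slides at 7 stages, and stages were compared across slides, linked only through T0.

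The deposited values are on a log2 scale, taken from their range of 3.92 to 18.9, with 1 column for each dye channel. The sorted values were identical in all 112 columns, which shows that the authors' deposited log2 values had been quantile-normalised over all samples; the median was 6.8 in each column. The submitters' processing notes name limma with no version. The background correction is not given in the sources used here, and the deposited table carries no detection calls, so no feature was called above or below background. Differences between low values can be compressed by the floor of the scale. Quantile normalisation also removes any change in total RNA signal, so each difference is relative to the other features of its sample.

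The table holds 15744 numbered features. No table used here pairs the numbers with genes, so tests were made per feature and not per gene. Probe averaging, the choice of the brightest probe, the check of the deleted genes and the tests of gene lists fixed in the plan were not run, and control and repeated spots were not set apart. Among 11808 features outside the lowest 25% by mean value, 564 (4.78%) had a near-identical partner (r over 0.99 across samples and mean within 0.5 on the log2 scale), so counts of features can exceed counts of genes.

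Values were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) with the 56 groups and the dye as fixed effects and the array as a random block, whose estimated correlation was -0.0264. All 112 samples entered one fit with 55 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each contrast at 0.05. For each mutant the contrasts were the mean difference from wild type over the 8 stages, the difference at each stage, and a moderated F-test of the 7 strain-by-stage interaction terms, called here the profile test. Wild type stages were each set against T0. Likeness of the mutants was measured by the correlation and covariance of their mean log2 differences across features, with 100 simulated draws of unchanged strains set against shared wild type samples, and again with the wild type samples split by dye.

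Replicate number equals dye in the labels, so samples with the same number share a dye, and the dye was kept as a replicate block. The check of this pairing gave a median correlation of 0.168 between replicate differences of 1540 pairs of groups, with 71.4% above 0.1 and a lowest value of -0.209. The dye term passed the threshold at 7315 features (46.5%).

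The rule for named features, fixed before the data were examined, took gene symbols; with none to be had it took the 2 largest rises and 2 largest falls per comparison among features past the threshold, for the mutants with the same sign in at least 7 of the 8 stages. Alternatives fixed in advance were leaving out the dye, ignoring the array correlation, further normalisation, a filter on dim features, a mean-dependent prior, the slide or array as a fixed block, additive models, fits of single mutants with wild type, a 2-fold minimum, other references for development, and leaving out each sample in turn. Closeness to stage profiles was chosen after seeing the data: values were centred per dye, the lowest 25% of features was left out, and each sample was correlated with the mean of the opposite-dye samples of the other strains at each stage.

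The procedure was tested on simulated data for 15744 features. For the mean of pks3 against wild type it recovered 8.96% of features changed by 0.5 on the log2 scale, 52.2% of those changed by 1 and 98.5% of those changed by 2, with 7.09% false calls. For wild type slug against T0 it recovered 0% at 1, 23.9% at 2 and 89.4% at 4, with 2.6% false calls. For the profile of pks14 it recovered 2.99% at 1, 31.3% at 2 and 84.8% at 4, with 5.76% false calls. The simulated noise was independent, with the same spread for a feature in all strains and no slide or array effect. Only 66 or 67 features were changed at each size. These shares therefore need not hold in the real data, where slides differ between stages and pks14 replicates were least alike. The number of arrays limits the precision: the median standard error was 0.247 to 0.249 for a mutant's mean difference and 0.7 to 0.704 for a wild type stage against T0.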

Results

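Expression was measured on 15744 array features in wild type Dictyostelium discoideum AX2 and in 6 strains that each lacked one polyketide synthase gene. Polyketide synthases build small molecules from acyl units, and in this amoeba some of the products act as developmental signals. pks1 and pks37 are also known as steely A and steely B, hybrid enzymes of which the latter makes the backbone of the stalk-inducing factor DIF. Each of the 7 strains was sampled at 8 stages, from the growing amoeboid cell through T0, loose aggregate, streaming, mound, slug and early culminant to the fruiting body, with 2 samples per strain and stage. Replicates of a group, which carried opposite dyes, correlated across features at a median r of 0.934 (range 0.797 to 0.981, 56 pairs). The median was lowest in pks14 (0.877) and highest in pks3 (0.948). Samples of different strains at one stage and opposite dye reached a median of 0.887 (294 pairs), and those of one strain at different stages 0.852 (390 pairs). Features are given by number because the tables used here do not pair them with genes, and the deleted genes were therefore not checked against the strain labels.

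The first comparison followed wild type development, with each stage set against T0. In the loose aggregate and the mound the same pair of features rose most: feature 7446 by 10.70 ± 1.28 (SE) and 12.10 ± 1.28 on the log2 scale, and feature 11737 by 11 ± 1.22 and 11.70 ± 1.22 (2 samples per group). In the fruiting body, feature 14842 was higher than at T0 by 12.50 ± 1.25 and feature 7238 by 11.80 ± 1.21. Feature 3645 fell by 5.53 ± 0.84 there and feature 6906 fell by 5.70 ± 0.92. Feature 3645 was also lower in growing cells than at T0, with a difference of -7.92 ± 0.84. Early culminants had the largest rises at features 14813 (11.50 ± 1.72) and 13599 (11.30 ± 1.40). In slugs, feature 15715 rose by 11.60 ± 1.72 while feature 11111 fell by 5.97 ± 0.93.

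Over the 7 stages the number of features that differed from T0 was smallest in streaming cells, with 502 (325 higher and 177 lower), and largest in slugs, with 1908 (1015 higher and 893 lower). Amoeboid cells differed at 957 features (462 higher), loose aggregates at 1050 (658 higher), mounds at 1491 (820 higher), early culminants at 1155 (688 higher) and fruiting bodies at 1391 (754 higher). The median absolute difference among features past the threshold lay between 2.75 and 3.11 on the log2 scale, and the largest rises exceeded the largest falls at every stage after T0. A test over all 8 stages found 3774 features (24%) that varied. Of these, 1143 (30.3%) had their lowest mean in amoeboid cells and 652 (17.3%) their highest mean there. T0 held the highest mean of 618 of them and streaming cells that of 525. The fewest features, 300, peaked in early culminants. Each stage other than T0 lay on its own slide, and the test over 8 stages was not repeated with the slide as a fixed block. The number of varying features and their stages of highest and lowest mean thus cannot be told apart from slide effects.

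Not every large difference was seen in both replicates. Feature 15052, the largest rise in amoeboid cells (6.49 ± 1.84, adjusted p = 0.0204), read 4.81 in replicate 1 and 17.1 in replicate 2, against 4.87 and 4.19 at T0. Feature 3230, the next largest, read 14.7 and 15.5 against 9.07 and 8.55.

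Each stage had its own slide, and the 2 wild type T0 samples lay on those of amoeboid and streaming cells. These 2 stages, which shared a slide with a reference sample, had the fewest features, so their small counts cannot be told apart from a slide effect. The wild type counts were therefore also taken with the slide as a fixed block. They were then 456 for amoeboid cells, 138 for loose aggregates, 517 for streaming cells, 236 for mounds, 674 for slugs, 47 for early culminants and 75 for fruiting bodies, with 97% or more of the features past the threshold keeping their sign at each stage, while the median standard error rose from 0.7 to as much as 1.38. The estimates moved too, with r across features between the fits of 0.623 in loose aggregates, 0.642 in fruiting bodies and 0.7 in mounds. In these stages 79 of 138, 49 of 75 and 140 of 236 features were among those reported. Larger standard errors lower both measures, and whether lost precision alone accounts for them was not tested. The order of the stages did not hold: with the slide as a fixed block, streaming cells had the second largest count and early culminants the smallest. Precision was unequal in that fit. The median standard error was 0.821 for amoeboid and 0.833 for streaming cells, which shared a slide with a T0 sample, and 1.16 to 1.38 for the other stages. The new order is therefore no ranking of the stages either.

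**Figure D1:**
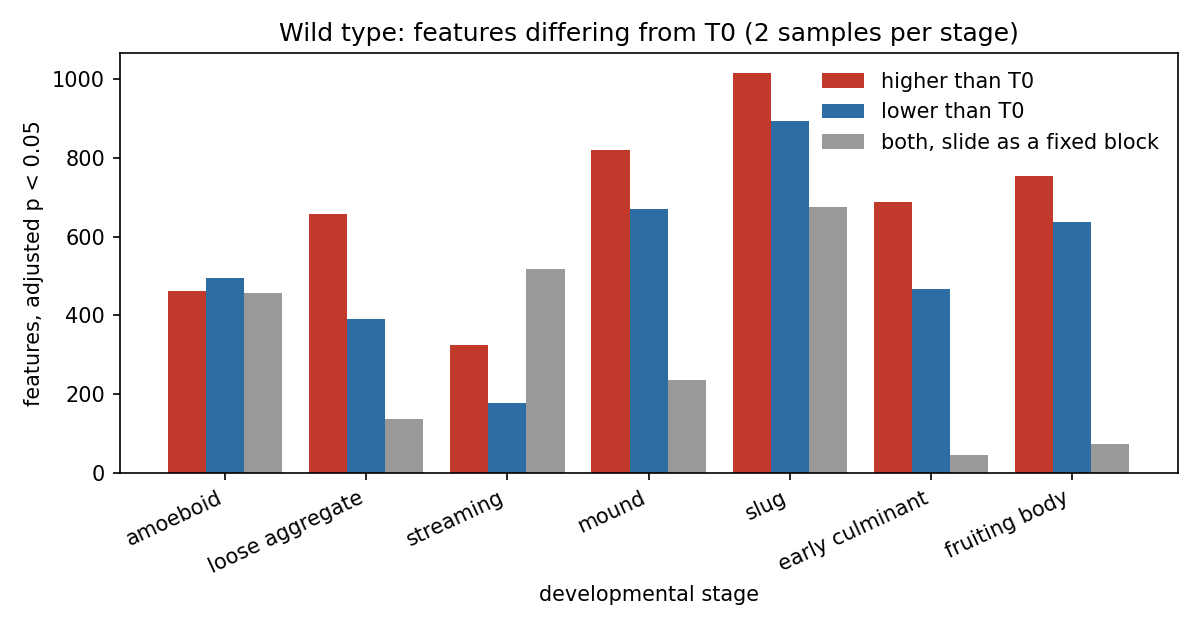
Number of features (y axis) that differed from T0 in wild type at each of 7 stages (x axis), with red bars for higher, blue bars for lower and grey bars for both directions together with the slide as a fixed block. Slugs had the most features, 1015 higher and 893 lower, and early culminants had 47 with the slide block, of which 22 were among the reported features.

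Each knockout was next compared with wild type over the mean of the 8 stages, 16 samples against 16. All 6 knockouts differed, and they differed by very unequal numbers of features. The widest differences were in pks2, with 4828 features (2263 higher and 2565 lower, 30.7% of those measured), and in pks14, with 4524 (2229 higher and 2295 lower). pks18 followed with 3394 (1596 higher and 1798 lower), pks3 with 2606 (1166 and 1440) and pks1 with 1805 (831 and 974). The smallest number was in pks37, with 1034 (488 higher and 546 lower). Only pks37 shared arrays with wild type samples of the same stage, at every stage other than T0. A contribution of the shared arrays to its small counts, here and at single stages, cannot be told apart. Features that differed by at least 2-fold numbered 2399 in pks2, 2191 in pks14, 1476 in pks18, 1109 in pks3, 928 in pks1 and 539 in pks37. In pks1 the 2-fold changes were mostly falls, 659 against 269 rises, and in pks18 971 against 505.

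One feature was among the largest falls of 3 knockouts. Feature 7162 had a mean log2 value of 11.1 ± 1.24 (SD, n = 16) in wild type and of 6.02 ± 1.20 in pks1, 5.62 ± 1.24 in pks14 and 5.22 ± 1.00 in pks37, differences of -5.06, -5.44 and -5.85. It stood between these in pks2 (8.11 ± 0.78), while pks18 had 10.1 ± 1.30 and pks3 11.5 ± 1.22. Feature 1216, the largest fall in pks14 (-5.53 ± 0.24, SE), was low in the same 4 knockouts: 7.27 ± 0.86 in pks14, 8.45 ± 1.09 in pks37, 9.22 ± 1.24 in pks1 and 10.5 ± 0.73 in pks2, against 12.8 ± 0.93 in wild type, 13.1 ± 0.70 in pks3 and 12.9 ± 0.73 in pks18.

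Other large falls had other patterns over the strains. Feature 10947 had a mean of 4.65 ± 0.71 in pks2 (highest sample 6.39) and lay between 10.9 and 12.4 in the other 6 strains (lowest sample 8.82), a difference from wild type of -6.31 ± 0.30 (SE). The lowest value of the table, 3.92, was reached in 3 of the 16 pks2 samples and 7 lay within 0.5 of it, so the size of this fall may be understated. The same caution applies to feature 7162 in pks37, where 2 of the 16 samples were at that value. Feature 12411 averaged 6.25 ± 1.39 in pks37 and 12.4 ± 2.31 in wild type, with pks1 between them at 8.77 ± 2.05. In pks18, features 3281 and 14917 differed from wild type by -4.80 ± 0.30 and -4.79 ± 0.30. Feature 3281 did not move one way in all knockouts: it averaged 14 ± 0.77 in wild type, 9.22 ± 2.30 in pks18 and 12.3 ± 1.55 in pks14, and 16.6 ± 0.65 in pks1 and 16.4 ± 1.18 in pks37. In pks3 the largest fall was smaller, -3.30 ± 0.29 at feature 446 (7.22 ± 2.12 against 10.5 ± 0.92), which was also low in pks2 (6.95 ± 2.22) and averaged 8.67 ± 1.59 in pks14.

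**Figure D2:**
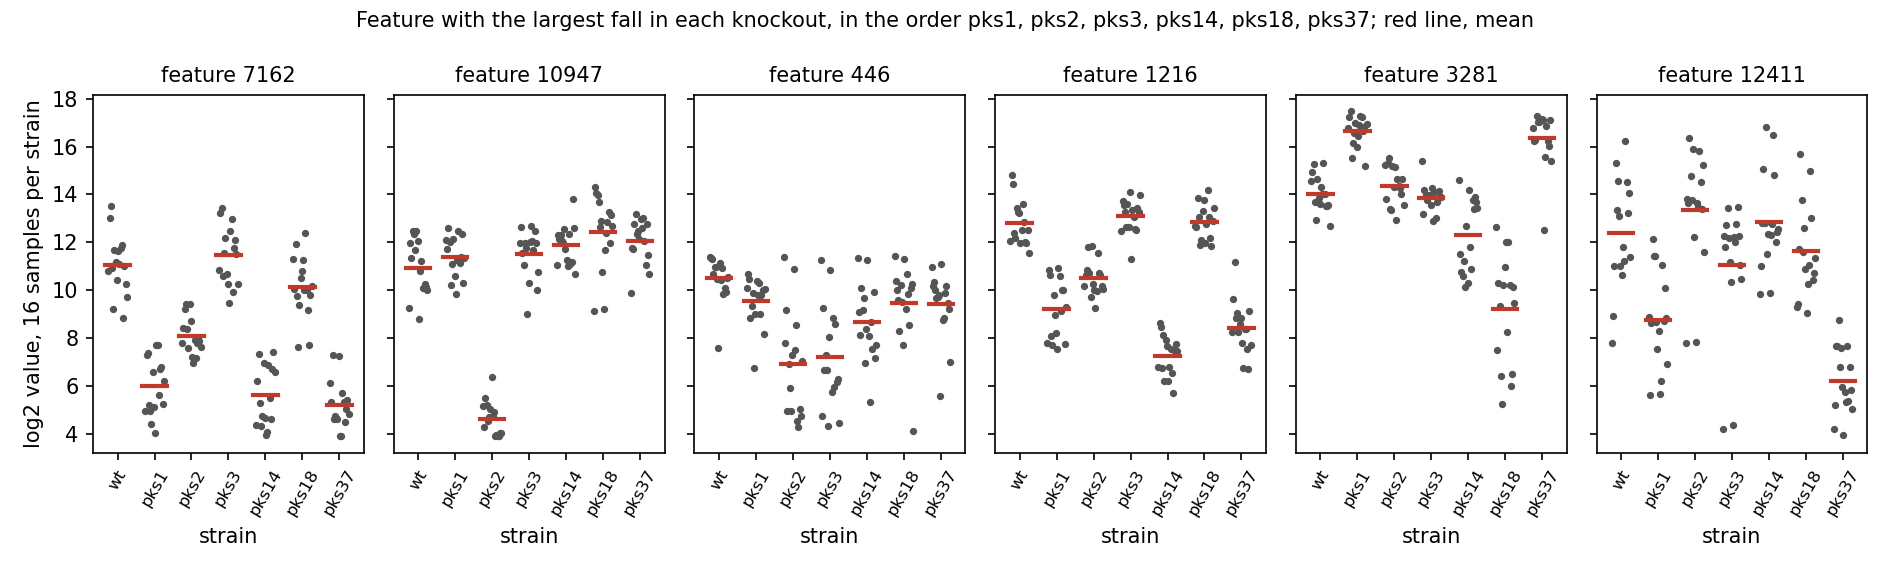
Log2 values (y axis) of all 16 samples of each strain (x axis, points; red lines are means) for the feature with the largest fall in each knockout. Feature 10947 is low in pks2 alone, at a mean of 4.65, whereas feature 7162 is low in pks1, pks14 and pks37, at 6.02, 5.62 and 5.22.

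In all 6 knockouts the largest rise was smaller than the largest fall. The largest rise in pks2 was 4.39 ± 0.33 at feature 14950 (13.5 ± 1.78 against 9.09 ± 1.34, SD, n = 16). In pks14, features 13746 and 6347 were higher by 3.74 ± 0.25 and 3.24 ± 0.20. pks37 had its largest rise at feature 11069 (3.29 ± 0.36), pks3 at feature 2616 (3.21 ± 0.54), pks1 at feature 9556 (3.15 ± 0.42) and pks18 at feature 11383 (2.41 ± 0.42). All of these rises had the same sign at 8 of 8 stages.

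Differences of the same direction in all 6 knockouts were rare. Among features past the threshold, 3 were higher and 2 lower in all 6, and 46 were higher and 53 lower in at least 5. Of the features that varied over wild type development 27.7% were called in pks1, and of those that did not 6.35%. These shares, whose difference was not tested, were 44.2% and 26.4% in pks2, 25.8% and 13.6% in pks3, and 42.7% and 24.3% in pks14. They were 26.3% and 20.1% in pks18, and 12.9% and 4.59% in pks37. The list of varying features and the knockout lists used the same wild type samples and the same estimate of spread per feature. This alone can raise the share among varying features in every knockout. The shares therefore do not show that the knockouts acted on developmental features in particular.

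These counts held within 1.5 times with the slide as a fixed block (2034 in pks1, 4224 in pks2, 2263 in pks3, 3871 in pks14, 2795 in pks18 and 1018 in pks37). With each array as a fixed block and additive strain and stage terms they fell to 49, 465, 40, 729, 837 and 149 in that order, while the median standard error rose from between 0.247 and 0.249 to between 0.34 and 0.492 and between 94.4% and 99.9% of the reported features kept their sign (r between the estimates 0.71 to 0.864). The balance of directions turned in 4 knockouts, with more rises than falls in pks1 (35 and 14), pks2 (272 and 193), pks3 (24 and 16) and pks37 (80 and 69). The order of the knockouts did not hold either: in that fit pks18 had the most features and pks3 the fewest. Of the features chosen by the naming rule, 5 no longer passed in it. Feature 9556 in pks1 did not shrink (3.15 ± 0.42 to 3.43 ± 0.84, SE, adjusted p = 0.0523), so its call ended through the larger standard error. The other 4 were nearer 0 and less precise: 2340 in pks1 (-3.87 ± 0.26 to -2.98 ± 1.00, adjusted p = 0.196) and, in pks3, 3395 (3.18 ± 0.55 to 2.28 ± 0.73, 0.163), 2616 (3.21 ± 0.54 to 1.28 ± 0.89, 0.66) and 12123 (-2.62 ± 0.41 to -1.06 ± 0.81, 0.701).

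The comparison was then made at each stage, which for 7 of the stages lies within one slide. Summed over the knockouts, the fewest differences were found in growing cells, but this held for single strains only in pks2 and pks37, and the stage with the most was not the same in each knockout. In amoeboid cells 611 differences were found over all 6 knockouts, from 6 in pks37 and 9 in pks3 to 198 in pks18. Early culminants had the most, 4818, followed by slugs with 4109. At each stage all 6 knockouts were set against the same wild type samples, so the stage totals also depend on those samples. Replicate 1 of wild type early culminants was closest to the fruiting body profile of the other strains (r = 0.239, own stage 0.174). Replicate 1 of wild type slugs was closest to their mound profile (0.47, own stage 0.23). How far these samples moved the stage totals was not tested. The largest number at any stage was 2626 in pks14 fruiting bodies (1227 higher and 1399 lower), where pks3 had 8 and pks18 had 91. pks2 differed most during aggregation, at 1694 features in loose aggregates and 1704 in streaming cells, followed by early culminants (1195) and T0 (991). pks3 also differed at these aggregation stages, at 835 and 771 features, and had 1296 in early culminants. pks18 peaked in slugs with 1322 and had 8 in loose aggregates. At T0 the strains lay on different slides, so counts there cannot be told apart from slide effects. pks1 and pks37, which each shared a slide with a wild type T0 sample, had 32 and 13 features at T0. The other knockouts, which shared none, had from 65 in pks3 to 991 in pks2.

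In pks1 the differences were concentrated in late stages and were mostly falls: 420 of 541 in slugs, 505 of 559 in early culminants and 117 of 129 in fruiting bodies, against 9 features in loose aggregates and 12 in mounds. Growing pks1 cells differed at 162 features, 91 of them lower. In pks37 they were few up to the mound (between 6 and 43 per stage) and rose to 323 in early culminants and 449 in fruiting bodies. Summed over stages the counts were 7456 in pks2, 6239 in pks14, 3728 in pks3, 2915 in pks18, 1490 in pks1 and 951 in pks37. This order did not hold when only a mutant's own samples and those of wild type entered the fit: pks3 then had 6674 and pks14 2702, with 11197 in pks2. Without replicate 2 of wild type early culminants the pks1 sum was 951. The pks37 sum was 1689 without replicate 1 of its own early culminants and 631 without replicate 1 of wild type fruiting bodies.

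**Figure D3:**
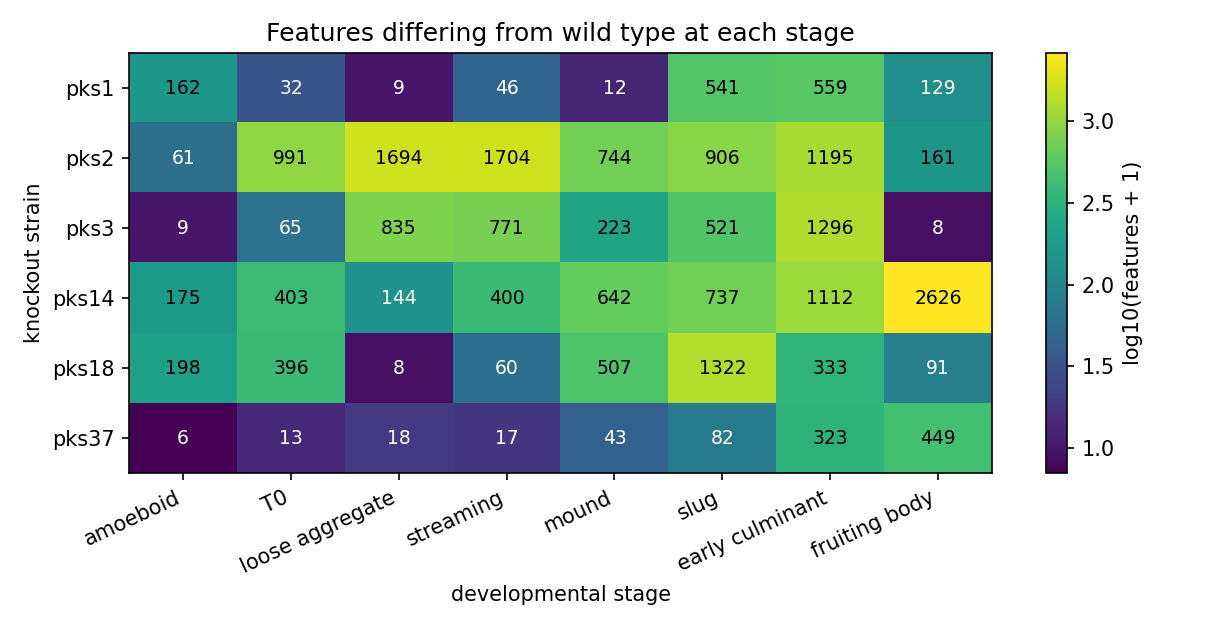
Number of features differing from wild type for each knockout (y axis) at each stage (x axis), with the colour on a log10 scale. The highest number is 2626 in pks14 fruiting bodies, and amoeboid cells range from 6 in pks37 to 198 in pks18.

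Whether a knockout changed the course of development, and not only the level of a feature, was asked by the profile test. The strain-by-stage terms passed the threshold at 843 features in pks2, 749 in pks3, 566 in pks14, 361 in pks18, 133 in pks1 and 39 in pks37. These counts were less stable than those of the mean. When only a mutant's own samples and those of wild type entered the fit they were 1879, 1709, 19, 195, 39 and 4 in the same order, so that the count of pks14 fell from 566 to 19. When samples of mutant and wild type were exchanged within stage and dye, 33 of 100 splits, the real one included, gave as many features in pks1, 39 in pks2, 17 in pks3, 54 in pks14, 38 in pks18 and 76 in pks37. Of 100 splits drawn because of that result, after the mean difference between the strains was removed, 11 gave as many features in pks14 and 35 in pks37, and 2 or fewer in the other 4 knockouts.

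The 6 knockouts were also compared with one another, through the correlation across features of their mean differences from wild type. Features are not independent replicates, and the wild type samples shared by all 6 raise each correlation: unchanged strains simulated against one set of wild type samples gave a mean r of 0.499 and a covariance of 0.0338. The 15 pairs had a median r of 0.298 and a median covariance of 0.0834. Most alike were pks14 and pks18 (r = 0.717, covariance 0.34) and pks2 and pks3 (r = 0.695, covariance 0.292). pks2 and pks14 had r = 0.546 and a covariance of 0.312. pks1 stood apart, with r between -0.185 (with pks14) and 0.0725 (with pks3). With different wild type samples for each mutant of a pair, split by dye, r was 0.601 for pks14 and pks18, 0.563 for pks2 and pks3, and -0.248 for pks1 and pks14.

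Of the features called in pks14 and pks18, 956 were higher in both and 1200 lower in both, where independent lists would share 226 and 262, and 38 were called in opposite directions. For pks2 and pks3 the numbers were 810 and 1040, against 168 and 235 for independent lists, with 29 opposite. For pks1 and pks14 they were 88 and 118, against 118 and 142, with 605 opposite. Unchanged strains simulated against shared wild type samples had no call in common, which sets no level for strains with real effects. With different wild type samples for each mutant, split by dye, 337 or 390 features were higher and 663 or 664 lower in both pks14 and pks18, depending on which dye went with which strain, and 399 or 391 were higher and 476 or 499 lower in both pks2 and pks3. Each of these was over 3 times the number for independent lists. Set directly against each other, pks14 and pks18 differed at 1884 features, the fewest of the 15 pairs, and pks2 and pks3 at 2475. pks1 differed from each of the other knockouts at 4431 to 6456 features.

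**Figure D4:**
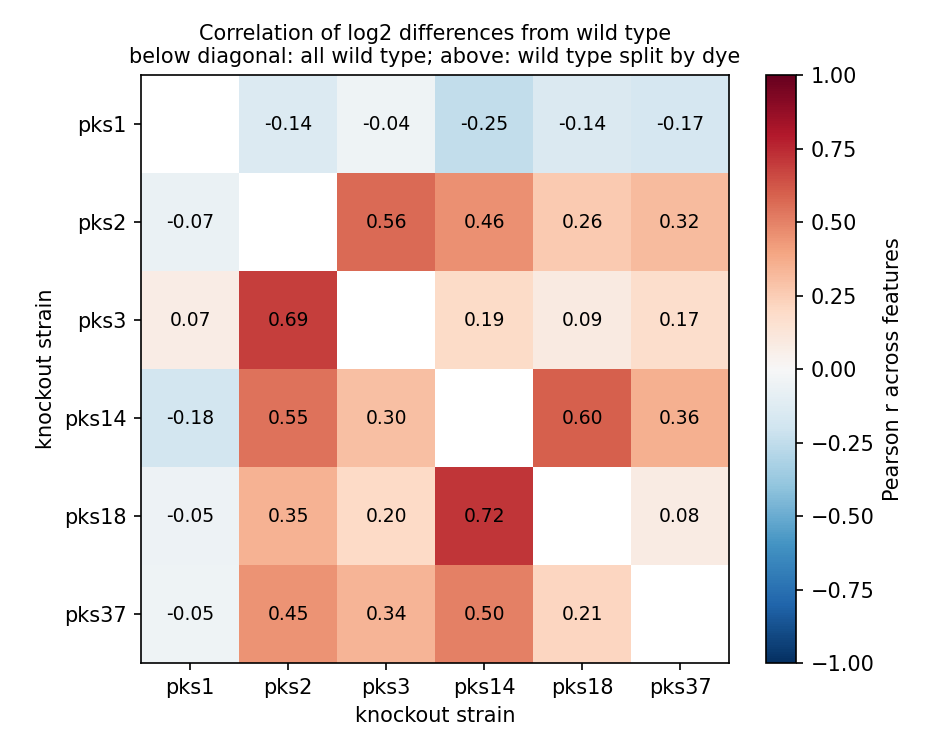
Pearson correlation across features (colour and number) of the mean log2 differences from wild type for each pair of knockouts (both axes), below the diagonal with all wild type samples and above it with the wild type samples split by dye. pks14 with pks18 (0.717) and pks2 with pks3 (0.695) are the highest, and pks1 lies between -0.185 and 0.0725.

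Finally, each sample was placed among the stages by its correlation with the stage profiles of the other strains, a comparison chosen after seeing the data. In all, 81 samples were closest to their own stage, where random placement would give 14. All 14 amoeboid and all 14 T0 samples were among them. Outside T0, the own-stage profile came from the sample's own slide and could include the other channel of its array. A shared slide or array may thus raise the number, so 14 is not the level without a stage effect. Own-stage samples numbered 15 of 16 in pks18, 14 in wild type and in pks2, 11 in pks37, 10 in pks3 and in pks14, and 7 in pks1. The difference between pks1 and wild type gave p = 0.0233 by Fisher's exact test (two-sided), or 0.14 after Benjamini-Hochberg adjustment over 6 knockouts, so it did not pass.

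In pks1, both early culminant samples were closest to the amoeboid profile (r = 0.626 and 0.615), as were both fruiting body samples (0.259 and 0.552), the first of them nearly as close to its own stage (0.232). Streaming replicate 2 (0.583, own stage 0.242) and slug replicate 1 (0.415) of pks1 were also closest to the amoeboid profile, and the other replicates of these stages were not. The 12 samples of the other strains had r with it between -0.632 and 0.133 as early culminants and between -0.533 and 0.0453 as fruiting bodies. In pks3, both loose aggregate samples (0.416 and 0.491) and both streaming samples (0.439 and 0.577) were closest to the T0 profile, and both mound samples to that of loose aggregates (0.528 and 0.613). The other strains' loose aggregates had r between -0.431 and 0.00689 with the T0 profile, but their streaming samples reached 0.538. With 7 strains, an exact permutation of the strain labels cannot give a one-sided p below 0.143, the value reached by pks1 at both stages and by pks3 at both stages. Both strains were picked at these stages for their closeness, so the choice fixed this value and it is no support. In pks14, both fruiting body samples were closest to the early culminant profile (0.595 and 0.479), the second of them nearly as close to its own stage (0.455; 0.466 for the first).

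**Figure D5:**
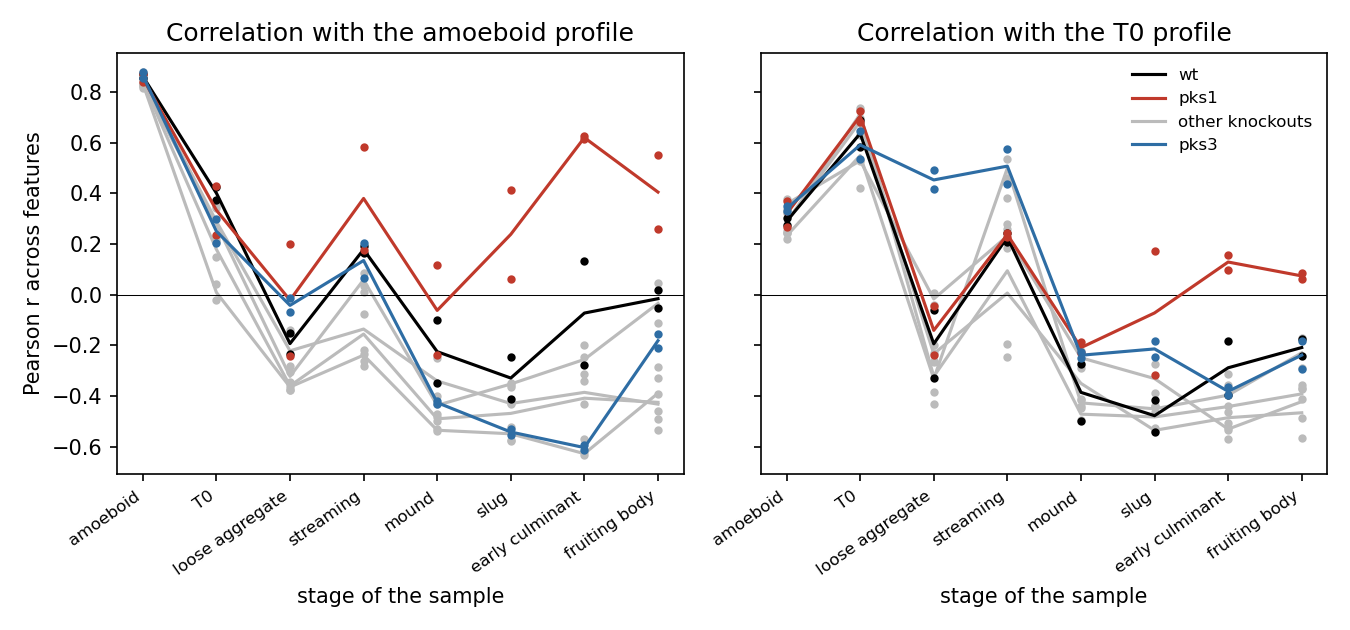
Pearson correlation across features (y axis) of each sample with the amoeboid profile (left) and the T0 profile (right) of the other strains, by the stage of the sample (x axis); points are samples, lines are means of 2. pks1 rises to 0.626 and 0.615 with the amoeboid profile as early culminant, and pks3 loose aggregates lie at 0.416 and 0.491 with the T0 profile.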

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

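The tests of a wrong label, of a shared array and of the level of amoeboid features for pks1, the shared-array tests of the mutant pairs, and the splits with the strain mean removed were chosen after related results had been seen. The other tests were set before their values were known, on patterns already seen. For 2 of them, on the direction of the pks1 and pks3 differences, the rule was changed after their values were known, so that a high r decides nothing. The rule for the shared-array tests was also made stricter afterwards: a shared array is excluded only where the predicted difference lies outside the 95% interval of the differences found.

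Stage-dependent differences from wild type were found by the interaction test in each knockout: at 133 features in pks1, 843 in pks2, 749 in pks3, 566 in pks14, 361 in pks18 and 39 in pks37. When samples of the mutant and wild type were exchanged within stage and dye, splits with as many features, the real one included, numbered 33 of 100 in pks1 (highest other 972), 39 in pks2 (3256), 17 in pks3 (2215), 54 in pks14 (3067), 38 in pks18 (1532) and 76 in pks37 (547). In these splits chance was not excluded for any of the 6. Over 3 times the real count was called by 13 of the other splits in pks1, 10 in pks2, 0 in pks3, 26 in pks14, 14 in pks18 and 32 in pks37, a limit chosen afterwards. Outside pks3 this points to a structure of the samples: exchanging labels at some stages only turns a constant difference between strains into one that depends on the stage. After each strain's mean difference was subtracted, the numbers were 2 of 100 in pks1 (highest other 144), 1 in pks2 (629), 1 in pks3 (456) and 1 in pks18 (221). These shares lie under 0.05 with no adjustment over the 6 knockouts, and in pks1 another split gave more features than the real one. In pks14 (11, highest other 1056) and pks37 (35, highest other 89) chance was not excluded. This second set was run because of the first, so both are given.

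For the mean over 8 stages, 1 of 100 splits, the real one, reached the count in each knockout: 1805 in pks1 against a highest other of 483, 4828 in pks2 against 2942, 2606 in pks3 against 872, 4524 in pks14 against 3081, 3394 in pks18 against 1865 and 1034 in pks37 against 198. Chance was excluded for these counts. The labels name no independent clones, so the gene deletion and other differences between the cell lines stay open alike.

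The first pattern weighed is that pks1 early culminants and fruiting bodies lay near the amoeboid profile. Values of the 14 amoeboid samples under a wrong label are argued against, since the highest r of the 4 samples was 0.626 and the lowest of those 14 was 0.817. Amoeboid RNA exchanged before hybridisation is not decided by this. The 14 samples shared a slide with the amoeboid profile, which may raise their r, while the pks1 samples lay on other slides. T0 samples, spread over slides, had r of 0.421 to 0.737 with their own profile. A simple admixture of growing cells is argued against too: the loss of late features would need 95.4% and 94.7% of such RNA in early culminants and the gain of amoeboid features 19.8% and 19%, with a median gap over the 4 samples of 75.6 percentage points; cells halted at another stage were not tested. A shared array cannot be told apart: the arrays of the replicate 2 samples also held pks14 samples of the same stage, whose r against that on other arrays was -0.247 against -0.569 in early culminants and -0.391 against -0.458 in fruiting bodies (mean difference 0.195), and those of the replicate 1 samples held T0 samples (0.237 and 0.209), which this test does not cover. Growing-cell expression kept at its full level is argued against as well (highest median -2.33 on the log2 scale, given below). In pks1, late features (chosen without pks1) differed from the other strains by medians of -4.44 and -4.24 in early culminants and -2.11 and -2.99 in fruiting bodies. Amoeboid features in pks1 fruiting bodies (-4.51 and -3.78 from the amoeboid level) were near wild type (-4.47 and -4.22). Nearness to the amoeboid profile there need not mean growing-cell expression. Another effect of the pks1 strain on development stays open and may explain the pattern.

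The second pattern is that pks3 loose aggregates and streaming cells lay near the T0 profile. A shared array cannot be told apart: the pks2 and pks37 samples on the same arrays exceeded those on other arrays by a mean r of 0.0747, but with an SD of 0.285 over 4 pairs, one of which (streaming pks37) differed by 0.502. Wrong labels cannot be told apart: the highest r of these samples with a pks3 T0 sample was 0.546 and the lowest 0.463, below but close to the 0.619 between the T0 replicates. An effect of the pks3 strain on the pace of aggregation could account for it and stays open.

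The third pattern is the likeness of pks14 with pks18 and of pks2 with pks3. Chance values of single wild type samples are argued against as the whole source, since r stayed at 0.601 and 0.563 with the wild type samples split by dye. A deviation common to both wild type replicates of a stage would stay in either part of this split. The replicates may be technical, so such a deviation is not covered. Neighbouring strains shared arrays, and a contribution of the shared array cannot be told apart from likeness of the strains in either pair. The difference in r between the same and different arrays was -0.0487 for pks14 and pks18 (SD 0.333 over 7 stages) and 0.0883 for pks2 and pks3 (SD 0.0969, exact two-sided sign-flip p = 0.0312, smallest possible 0.0156). Effects shared by the deletions, or by the lines they were made in, may underlie the rest and were not separated.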

How the results depend on the processing

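The dye term per slide, leaving out each stage, the 6 stages before early culmination, a stricter filter on dim features and the settings for stage profiles were added after seeing the data. Further quantile normalisation and median centring move nothing on values that were already quantile-normalised, so they test nothing. The check of deleted genes, the gene lists and the brightest probe were not run, since no table used here pairs features with genes. Signal over background is not given in the sources used here, so its limit is open. Ignoring the array correlation, the mean-dependent prior, the planned dim filter and a dye term per slide left the mean, profile, summed stage and wild type counts within 1.5 times, as the stricter filter did for the mean counts, the only ones it was run on. The 5 other settings for stage profiles placed 73 to 87 samples closest to their own stage.

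Without the dye as a replicate block, the profile count of pks37 was 17 and its summed stage count 479; the block changed no other count by over 1.5 times. With the slide as a fixed block the profile count of pks37 was 25, and the wild type counts were 456 for amoeboid cells, 138 for loose aggregates, 236 for mounds, 674 for slugs, 47 for early culminants and 75 for fruiting bodies. With the array fixed and strain and stage additive, the mean counts were 49 in pks1, 465 in pks2, 40 in pks3, 729 in pks14, 837 in pks18 and 149 in pks37. Both blocks leave fewer comparisons within a block, and their standard errors are larger. Additive strain and stage terms alone gave 1002 in pks1 and 458 in pks37; the cause was not tested. A 2-fold minimum removes small differences by construction and left 928, 2399, 1109, 2191, 1476 and 539 (pks1, pks2, pks3, pks14, pks18, pks37).

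With the mutant's and wild type's samples only, the profile counts were 39, 1879, 1709, 19, 195 and 4 in that order, and the summed stage counts 962 in pks1, 11197 in pks2, 6674 in pks3, 2702 in pks14 and 453 in pks37. Each pair then has its own estimate of spread, and replicates were least alike in pks14 and most alike in pks3. The 6 stages before early culmination gave mean counts of 976 in pks1, 2604 in pks14 and 233 in pks37, with fewer samples.

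For wild type development, amoeboid cells as reference gave 1913 for loose aggregates and 1225 for streaming cells. The mean over all 7 strains, with more samples, gave 7191, 5559, 4368, 7052, 7075, 7719 and 7243 from amoeboid cells to fruiting bodies. Additive terms with the slide fixed gave 2627 for amoeboid cells, 1688 for loose aggregates, 1099 for streaming cells, 2794 for early culminants and 3365 for fruiting bodies.

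Splitting the wild type samples by dye removes shared chance values of single samples, though not those common to both replicates. It lowered r to 0.563 for pks2 and pks3, 0.316 for pks2 and pks37, 0.0905 for pks3 and pks18, 0.173 for pks3 and pks37, 0.601 for pks14 and pks18, 0.357 for pks14 and pks37 and 0.0827 for pks18 and pks37.

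Leaving out single samples or stages assumes that the lone sample left in a group varies like the other groups. Mean counts then ranged from 1108 to 2047 in pks1, 4021 to 4948 in pks2, 1893 to 3057 in pks3, 3511 to 4678 in pks14, 2462 to 3603 in pks18 and 444 to 1325 in pks37. The lowest in pks1 was without slugs, and pks37 had 575 without early culminants and 444 without fruiting bodies. No single sample moved a mean count by over 1.5 times. Summed stage counts ranged from 951 to 2019 in pks1 (951 without wild type early culminant replicate 2), 6409 to 7524 in pks2, 2583 to 3962 in pks3, 4870 to 7283 in pks14, 1996 to 3399 in pks18 and 631 to 1689 in pks37 (1689 without its early culminant replicate 1, 631 without wild type fruiting body replicate 1).

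Profile counts ranged from 629 to 1115 in pks2, where no sample moved them by over 1.5 times. The range was 451 to 1011 in pks3, with 476 and 451 without early culminant replicate 1 of pks3 and of wild type. It was 208 to 628 in pks18: 236 without its amoeboid replicate 1, 209 without slug replicate 2, 628 without T0 replicate 2, and 224 and 208 without wild type amoeboid replicate 1 and slug replicate 1. It was 85 to 393 in pks1: 210 without its T0 replicate 1, 393 without streaming replicate 2, 262 without slug replicate 2, and 85, 235 and 348 without replicate 2 of wild type early culminants, mounds and slugs. It was 273 to 1276 in pks14: 337 and 273 without its fruiting body replicates 1 and 2, 1276 and 1029 without streaming replicates 1 and 2, 1020 without early culminant replicate 2, 904 without slug replicate 2, 297 without either wild type fruiting body, and 876 and 859 without replicate 2 of wild type mounds and slugs. It was 10 to 173 in pks37: 128 and 102 without its early culminant replicates 1 and 2, 21 without fruiting body replicate 1, 84 without streaming replicate 1, 65 without T0 replicate 2, 19 without wild type early culminant replicate 1, 13 and 10 without wild type fruiting body replicates 1 and 2, 64 without wild type T0 replicate 1, and 90 and 173 without replicate 2 of wild type mounds and slugs.

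Wild type counts fell whenever one of the 2 samples of a stage was left out. They ranged from 239 to 716 for amoeboid cells (560 and 239 without replicates 1 and 2), 568 to 916 for loose aggregates (568 without replicate 1), 229 to 483 for streaming cells (261 and 229 without replicates 1 and 2), 963 to 1241 for mounds (963 without replicate 1), 1087 to 1549 for slugs (1087 without replicate 2), 370 to 907 for early culminants (370 without replicate 2) and 670 to 1089 for fruiting bodies (670 without either). Without T0 replicate 1 they were 485 for amoeboid cells, 619 for loose aggregates, 306 for streaming cells, 1099 for slugs, 701 for early culminants and 795 for fruiting bodies.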

Other observations

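The correlations of direction below were taken on patterns already seen and largely restate them, so they support no hypothesis.

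Some features separated a knockout from wild type in every sample and at every stage. In pks14, 41 features were lower in all 16 samples than in any of the 16 wild type samples and 8 were higher. pks37 had 8 lower and 0 higher, pks18 had 7 lower and 0 higher, pks1 had 3 lower and 7 higher, and pks2 had 1 lower and 6 higher. pks3 had 0 in either direction, although limma called 2606 of its features. With labels exchanged within stage and dye as if all samples were independent, chance gives a share of at most 3.05e-05, or 0.48 features per knockout in both directions together. Features are not independent, and replicates may not be either, so no p-value is given.

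That pks1 cells keep the expression of growing cells at its full level is argued against. Bright features (log2 level of 10 or more in amoeboid cells) at least 16 times higher in amoeboid cells than at the late stage in the other strains had a median log2 level below the amoeboid one in all 4 pks1 samples: -2.33 and -2.40 in early culminants (upper quartiles -1.72 and -1.74, 34 features) and -4.51 and -3.78 in fruiting bodies (upper quartiles -3.46 and -3.09, 20 features). In wild type they were -2.85 and -3.74, and -4.47 and -4.22. Wild type took part in choosing these features and in the amoeboid level while pks1 did not, so pks1 can stand higher through the choice alone. Retention in part, in early culminants, stays open. Across features, the difference of pks1 from wild type followed the difference between amoeboid cells and the same stage in the other 5 knockouts, with r of 0.768 in early culminants and 0.565 in fruiting bodies. High values were to be expected from the closeness of these samples to the amoeboid profile, so they are no independent evidence. The measure was not confined to late stages in pks1: it was 0.532 in slugs, 0.436 in streaming cells, 0.32 in loose aggregates and 0.275 in mounds. In early culminants of the other knockouts it was -0.538 in pks2, -0.557 in pks3, -0.508 in pks14, -0.309 in pks18 and -0.288 in pks37. Wild type enters all of these differences, and its early culminant samples differed from each other (r of 0.133 and -0.277 with the amoeboid profile), so part of the contrast between pks1 and the other knockouts may come from wild type.

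For pks3 the hypothesis is slower aggregation. The difference of pks3 from wild type followed the difference between T0 and the same stage in the other 5 knockouts with r of 0.646 in loose aggregates and 0.543 in streaming cells, and it was 0.123 in mounds. These values repeat the closeness to T0 already described and leave the hypothesis open. The measure was not particular to pks3: in pks1 it was 0.265 in loose aggregates, 0.331 in streaming cells, 0.319 in mounds and 0.613 in early culminants. It was 0.359 in streaming pks18 cells and 0.234 and 0.222 in pks2 loose aggregates and streaming cells.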
